A study of Mus musculus with 4 samples.

How the data were processed

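Cells were captured with the 10x Genomics 5' version 2 chemistry from dura and brain of C57BL/6J mice, and each of the 5 groups of mice was labelled with its own TotalSeq-C hashtag antibody, per the labels' protocols. Mice were perfused, tissue of 5 mice was pooled per group, and dura was digested with Liberase DH and DNase I, each at 0.2 mg/ml. The brain was homogenised on ice, passed through a 70 um strainer and separated on 37% Percoll before CD45+CD11b- cells were sorted. Of the 4 libraries, 1 held 3 tags, 1 held 4 and the other 2 held 1 each.

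The deposited matrices hold UMI counts for 32285 genes and for the hashtags, as whole numbers without normalization, for the barcodes that Cell Ranger 6.0.2 called as cells, per the file headers. The submitters' processing notes name Cell Ranger, the mm10 build and Seurat 4.0.0, and no value from Seurat entered here. Antigen receptor libraries were not used here. All 435 gene IDs printed or listed in the tables were found in the GENCODE M21 annotation of GRCm38, from which coordinates were taken. Xist, a transcript of the inactive X chromosome, had 0 UMIs in every dura pool and 3 in the brain pool.

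Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept, which removed 22, 492, 12 and 0 barcodes in the order of the libraries (CD45+ dura of 3 pools, CD45- dura, CD45+ dura of MCAO 3 weeks, brain). Hashtag calls for the first 2 libraries came from HTODemux in Seurat 5.3.0 under R 4.3.3, at quantile 0.99 and seed 42. In the CD45+ library 9.57% of barcodes were called doublets and 23.1% were called negative, and in the CD45- library 2.67% and 36.7%. Cells without a call were left out. The other 2 libraries were 1 pool each and all their cells were kept. Within each library, the cells with the highest Scrublet scores (scanpy 1.11.5), at a rate of 0.8% per 1000 cells, were removed as doublets, 321, 26, 582 and 911 in that order. A doublet of cells from the same pool can escape both steps, and RNA from lysed cells was not subtracted.

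Each library was clustered on its own with 2000 variable genes, 30 principal components, a shared-neighbour graph of 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. A cluster was named by the marker list with the highest score. It stayed unnamed with a score below 0.2, with fewer than 3 markers detected in 10% of its cells, with more markers of another family among its 10 leading genes, or with a median depth below the library median divided by 3 and no marker among those genes. T cells, NK cells and ILCs were clustered again and named by subset, with a marker of the subset required among the leading genes. The marker lists were fixed before the data were examined. The naming rules were not: they went through 3 versions, all written after clusters were seen, and the last added 3 rules for subsets that were aimed at particular subclusters. Monocytes and conventional DCs were merged into 1 class after the clusters were seen, because the same leading genes were named differently in different libraries. Named cells numbered 3802 of 4070, 893 of 1077, 6607 of 7798 and 9200 of 9763 in the order of the libraries, phagocyte clusters without a class among them, and unnamed cells stayed in the denominators of shares.

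Shares of cells carry exact 95% binomial intervals and ratios of shares exact conditional 95% intervals, for counting error only. For expression, raw UMI counts were summed over the cells of a class and pool and scaled to CPM of the sum. The ratio of 2 sums carries an exact conditional 95% interval and its log2 a prior count of 0.5. Classes needed at least 50 cells in both pools (30 for CD45- cells) and genes at least 30 UMIs in the 2 sums together. Where a pool had 0 UMIs, the least fold was computed from the 3 counts that 0 counts allow. The median log2 ratio over all genes of a class lay between -0.18 and 0.09 in every comparison. No test, standard error or count of changed genes was made from cells.

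Genes were named by a rule fixed before the data were examined: an absolute log2 ratio of at least 1, the same direction with a log2 ratio of at least 1 against the other sham pool where 1 library held both, and rank by the bound of the interval nearest to no difference, the first 5 higher and first 5 lower per class. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T-cell receptor genes and genes with only a model name were left out. Of the 190 genes named, 33 lead a cluster of their own class, 33 had less than 10% of the level seen in another class, 34 were carried by 10 or fewer cells and 62 had over 20% of their UMIs in 1 cell. Most genes of these kinds are not printed, and the thresholds of the last 2 kinds were set after the counts were seen. Genes of the lists below are also named.

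The 25 gene lists and 7 lists of markers of other cells, 340 genes of which 338 were in the matrices, were fixed before the data were examined. For each list with at least 5 measured genes the median log2 ratio was set against 10000 random lists of the same size drawn from 20 expression bins, and its interval came from 1000 Poisson redraws of the counts. Of 247 medians in the comparisons, 140 lay past the 2.5 or 97.5 percentile, and 105 of these belonged to lists tied to the class. The lists described were mainly chosen from these 105, and not all of the 105 are printed. Another 35 were not tied and are not described. The threshold, the tie of lists to classes and the rule for the largest list of a class were set after the medians were seen. In the ratio of the sham pools, 28 of 52 tied medians lay past the same percentiles, the largest at 1.57, so a percentile alone does not set MCAO apart from a difference between pools.

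The method was tested on simulated data, made by redrawing the counts of 4 comparisons with fold changes of 2 or 4 planted in some genes. Between 98.9% and 100% of genes with a true fold of 4 passed the size rule, between 45.4% and 52.6% of those with a true fold of 2, and between 1.45% and 6.05% of unchanged genes. Intervals held the true ratio for between 95.8% and 96.3% of all measured genes, changed genes included. A list with a true log2 ratio of 1 had medians between 0.95 and 1.11, and of 100 unchanged lists between 2 and 4 lay past the percentiles. The unchanged lists were drawn at random from the measured genes, so a low number was built in. The redraws held counting error only, without differences between pools, in cell mixture or shared by genes of a list. They do not show how often lists pass between real pools without stroke, where 28 of 52 tied medians did.

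Alternatives fixed before the data were examined were a looser filter (200 genes, 20% mitochondrial UMIs) and a stricter filter (500 genes, 5%), no Scrublet, hashtag calls from a Gaussian mixture, Leiden resolutions 0.5 and 2, joint clustering of the CD45+ libraries without integration, only tag-positive cells in the libraries of 1 pool, edgeR 4.0.16 TMM scaling, totals without the 20 most abundant genes, at least 10 or at least 100 UMIs per gene, and every cell thinned to 1000 UMIs. Named cells as the denominator, subset naming without the 3 extra rules, brain CD4 T cells without the subcluster with Cd8b1 among its leading genes, unnamed clusters counted in the family of their leading genes, and gene ratios without the cell with the most UMIs were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for the rest.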

Results

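The dura mater, the tough outer membrane around the brain, and the brain itself were profiled by droplet single-cell RNA sequencing in C57BL/6J mice after middle cerebral artery occlusion (MCAO), a surgical model of ischaemic stroke, or after sham surgery. Dura was taken 1 week and 3 weeks after either operation, on the ipsilateral side and away from the venous sinuses, and brain leukocytes were taken only 3 weeks after MCAO. The cells of 5 mice were pooled in each group, so every group was 1 pool. A first library held CD45+ dura cells, the leukocytes, of the Sham 1 week, MCAO 1 week and Sham 3 weeks pools (6301 barcodes, 40915514 unique molecular identifiers, UMIs). A second held CD45- dura cells, the non-leukocytes, of all 4 dura pools (2138 barcodes, 17420754 UMIs). Another held CD45+ dura cells of the MCAO 3 weeks pool (8392 barcodes, 69929983 UMIs), and the last held CD45+CD11b- brain cells of the MCAO 3 weeks pool (10674 barcodes, 49641173 UMIs). The median depth per barcode was 3410, 6417, 7097 and 3651 UMIs in that order. After filtering and assignment of cells to pools by hashtag antibodies, 4070, 1077, 7798 and 9763 cells remained. There was no replicate pool, so no test was run and no p-value is given. Intervals in parentheses are 95% intervals that cover counting error only. The ratio of the Sham 3 weeks pool to the Sham 1 week pool was the only measure of how far pools without stroke differed. It is given as sham over sham beside shares of the first library at 1 week and beside many list medians of the dura. Other list medians are printed without such a measure.

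The first comparison asked which leukocytes made up the dura after stroke. B-lineage cells were the largest family in the Sham 1 week pool and one of the smallest in the MCAO 1 week pool. They were 37.0% of 1367 cells (506 cells) in the Sham 1 week pool, 4.20% of 1761 cells (74 cells) in the MCAO 1 week pool, 24.5% of 942 cells (231 cells) in the Sham 3 weeks pool and 4.57% of 7798 cells (356 cells) in the MCAO 3 weeks pool. At 1 week the share was 8.81 times lower after MCAO (6.89 to 11.4), against a sham over sham ratio of 0.662 (0.565 to 0.776), and it was also lower than in the Sham 3 weeks pool, at a ratio of 0.171 (0.13 to 0.224). Phagocytes, which here are macrophages, monocytes, conventional dendritic cells (DCs) and phagocyte clusters given no class, were 28.6% and 63.0% of cells in the sham and MCAO pools at 1 week, a ratio of 2.20 (1.96 to 2.48) against 1.44 (1.25 to 1.67) for sham over sham.

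Within the B lineage at 1 week, the cells were spread differently over the clusters. Precursor-like B cells, led by Rag1, which encodes a recombinase of antigen receptor genes, were 56 cells in the Sham 1 week pool, 24 in the Sham 3 weeks pool and 0 of 1761 in the MCAO 1 week pool. A cluster led by Ms4a1, Spib and Vpreb3 had 299, 158 and 11 cells in the same order, and a cluster led by Fcer2a and Ighd, genes of mature B cells, had 151, 49 and 63. At 3 weeks after MCAO, precursor-like B cells were 70 of the 356 B-lineage cells. Among phagocytes, macrophages were 1.84 times higher after MCAO at 1 week (1.58 to 2.15; sham over sham 1.50) and the class of monocytes and DCs was 2.83 times higher (2.35 to 3.43; sham over sham 1.25). T cells, natural killer (NK) cells and innate lymphoid cells (ILCs) together had a ratio of 0.754 (0.627 to 0.906; sham over sham 0.981). Neutrophil-lineage cells were lower, at a ratio of 0.404 (0.302 to 0.538), and sham over sham was 0.685 (0.506 to 0.921). Mast cells and basophils had a ratio of 2.89 (1.79 to 4.87), close to the sham over sham ratio of 2.44. Cells without a hashtag call, which were left out, were 2.29% of B-lineage cells, 6.59% of T cells, NK cells and ILCs, 27.0% of phagocytes, 43.6% of neutrophil-lineage cells and 50.9% of mast cells and basophils in this library. The lowest tag count among called barcodes was 531 for MCAO 1 week, 65 for Sham 1 week and 38 for Sham 3 weeks. Barcodes without a call had a median of 80 counts of the MCAO 1 week tag, against 22 in those of either sham pool. The loss may therefore fall more on the MCAO pool, which bears on the neutrophil-lineage ratio. It was tested only for B-lineage cells.

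At 3 weeks the B-lineage share was 5.37 times lower in the MCAO pool than in the sham pool (4.53 to 6.36) and the neutrophil-lineage share had a ratio of 0.32 (0.241 to 0.429), or 0.59 with an unnamed MCAO cluster of 152 cells with neutrophil genes. The phagocyte share was 57.1% against 41.3%, a ratio of 1.38 (1.25 to 1.54), with monocytes and DCs at 1.78 (1.49 to 2.16) and macrophages at 1.03 (0.905 to 1.18), and 465 MCAO phagocytes had no class. The joint share of T cells, NK cells and ILCs had a ratio of 1.01 (0.859 to 1.20), or 1.47 with unnamed MCAO clusters of 557 and 66 cells with T cell genes, but within it NK cells were 9.96% against 34.4% and ILCs 7.25% against 32.5%. The MCAO 3 weeks pool was a library of its own, so library and stroke cannot be told apart at 3 weeks, and 15.3% of its cells against 4.56% stayed unnamed. The direction for mast cells (ratio 0.571) and for monocytes and DCs at 3 weeks reversed under other settings, and all shares were shares of sorted cells.

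**Figure D1:**
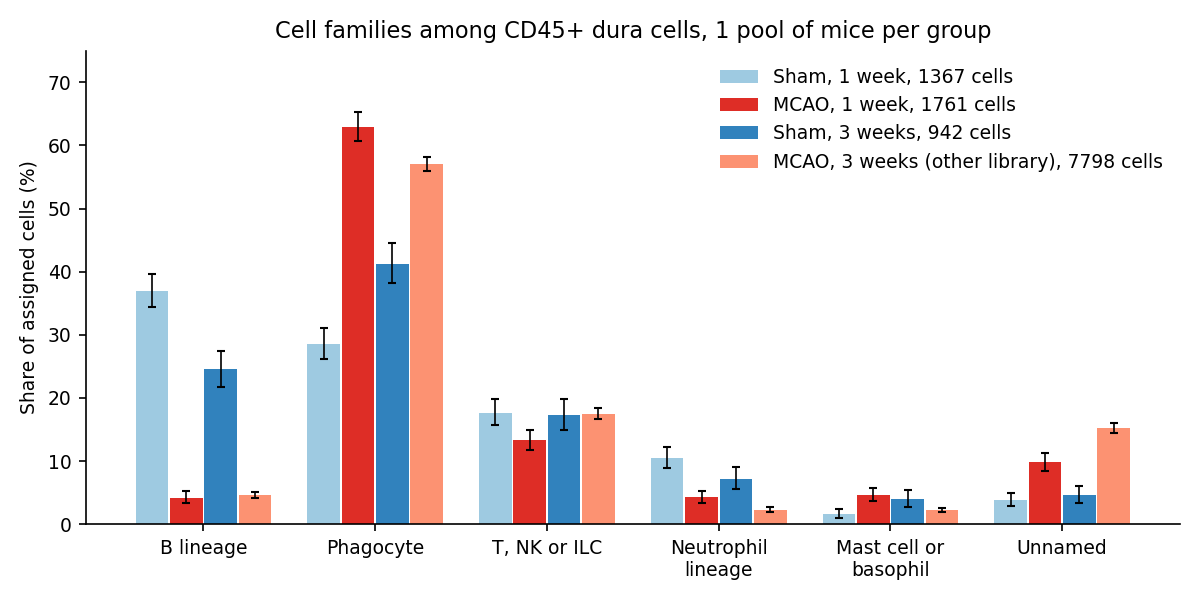
The bars give the share in percent (y axis, from 0) of each cell family (x axis) among the assigned CD45+ dura cells of the 4 pools, and the error bars are exact 95% binomial intervals. The B-lineage bars of the MCAO pools stand at 4.20% and 4.57%, below 37.0% and 24.5% in the sham pools.

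The second comparison asked how gene expression in each dura leukocyte class differed 1 week after MCAO, within 1 library. Of the 37 list medians measured in MCAO over sham and also in sham over sham, 23 and 20 lay outside the range of random lists, with median sizes of 0.49 and 0.14 over all 37. In macrophages the genes of the MHC class II pathway, which presents antigen to CD4 T cells, were lower in the MCAO pool: all 9 measured members were lower, with a median log2 ratio of -1.66 (-1.69 to -1.56; sham over sham 0.24). H2-Aa, a chain of the class II molecule, was 3.15 times lower (3.06 to 3.25), H2-Eb1 was 4.06 times lower (3.94 to 4.18), Cd74, the invariant chain, was 3.16 times lower (3.11 to 3.21), and Ciita, the master regulator of the pathway, was 3.27 times lower (2.39 to 4.45). Against the Sham 3 weeks pool the median was -1.88. The single genes named by the size rule included Retnla, a marker of alternative activation, at 46.5 times higher (22.5 to 116; UMIs in 45 of 579 cells), the membrane protein gene Emp1 at 22.3 times higher (12.7 to 43.2), the cytolinker gene Plec at 16.1 times higher (9.72 to 28.8) and the calcium-binding protein gene S100a4 at 7.53 times higher (5.83 to 9.89). Ctsk, a protease of osteoclasts, was 80.7 times higher (14.4 to 3194), with UMIs in 41 MCAO cells and 1 sham cell, and also leads an unnamed cluster of 34 cells. Ddit4, a stress gene that restrains mTOR signalling, was 12.4 times lower (9.71 to 15.9), the matrix protease gene Mmp9 was 12.2 times lower (9.53 to 15.8), Egfl7 was 11.5 times lower (7.89 to 17.1) and Adm, which encodes adrenomedullin, was 14.6 times lower (7.41 to 30.6).

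Other groups in the same macrophages were higher in the MCAO pool. The interferon response list had 17 of 19 members higher, with a median log2 ratio of 0.60 (sham over sham -0.06), among them Rsad2 at 4.25 times higher (2.69 to 7.11) and Isg15 at 2.42 times higher (1.99 to 2.97). The lipid handling and phagocytosis list had 10 of 16 members higher and a median of 0.76 (sham over sham 0.16): the osteopontin gene Spp1 was 7.26 times higher (4.72 to 11.8), the lipoprotein lipase gene Lpl 5.88 times higher (4.49 to 7.86) and Lgals3 4.42 times higher (3.88 to 5.06), while the scavenger receptor gene Cd36 was 2.91 times lower (2.52 to 3.35) and Apoe 1.55 times lower (1.53 to 1.57). Cell cycle genes had a median of 1.40, or 1.11 with the 2 genes without sham UMIs at their bound, and 14 of 15 members were higher. The inflammatory list was higher by a median of 0.51 (sham over sham 0.30), with the chemokine gene Cxcl2 at 2.78 times higher (2.63 to 2.94) and the cytokine gene Tnf at 1.49 times lower (1.31 to 1.69). The class was not the same mixture in the pools: 414 of the 579 MCAO macrophages lay in a cluster led by Ccl8, Folr2 and Lyve1 that held 14 of the 244 sham macrophages, and 179 sham and 83 MCAO macrophages lay in a cluster led by Pla2g2d, Vcam1 and Cd163. A further macrophage cluster, led by the interferon genes Ifit3 and Rsad2 and counted under the other observations, held more MCAO than sham cells. No interferon median without it was computed. MCAO macrophages held 12146 UMIs per cell and sham macrophages 4544. The lowest MCAO 1 week tag count of a called barcode was 531, against 65 and 38 for the Sham 1 week and Sham 3 weeks tags. Phagocytes of this library without a call had a median of 1100 UMIs, against 7931 in called ones. Shallow MCAO cells may thus have been left out more often than shallow sham cells.

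In monocytes and DCs the inflammatory list had 14 of 15 members higher in the MCAO pool at 1 week, with a median log2 ratio of 0.94 (0.72 to 1.19; sham over sham 0.07). Il1rn, the antagonist of the interleukin-1 receptor, was 7.51 times higher (3.92 to 16.5), Cxcl2 was 4.71 times higher (4.15 to 5.37) and Il1b was 2.57 times higher (2.31 to 2.86). The C-type lectin gene Clec4n was 13.7 times higher (8.99 to 21.8) and the syndecan gene Sdc4 was 14.4 times higher (8.81 to 25.2). Ddit4 was 8.78 times lower (6.09 to 12.7), Mgst1 was 6.87 times lower (5.56 to 8.49) and Nfe2 was 6.90 times lower (4.56 to 10.5). MHC class II genes, which were lower in the macrophages of this pool, had 8 of 10 members higher here and a median of 0.50 (sham over sham 0.14). The cell cycle median of 0.95 was smaller than the sham over sham median of 1.57. A cluster led by Cd209a and Ccl17 held most of the 525 MCAO cells and 36 of 144 sham cells, and a cluster led by Ace and Apoc2 held 102 and 77.

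The B-lineage cells left in the MCAO 1 week pool had more MHC class II RNA: all 10 members were higher, with a median log2 ratio of 1.06 (0.83 to 1.21; sham over sham -0.13), and H2-Eb1 was 2.64 times higher (2.44 to 2.86). The list of B-cell maturation and activation had 8 of 9 members higher and a median of 0.82 (sham over sham -0.29), led by Nr4a1, an immediate early gene induced by receptor signalling, at 3.41 times higher (2.95 to 3.95). Plaur, the urokinase receptor gene, was 4.37 times higher (3.12 to 6.07). The B-cell development list had 11 of 11 members lower, with a median of -3.10 (-3.66 to -2.55; sham over sham -0.01). Of these, 5 had 0 UMIs in the MCAO pool, and with them set at the 3 UMIs that a count of 0 allows the median was -1.21, and it was -0.62 at a finer clustering. The light chain partner gene Vpreb3 was 3.32 times lower (2.65 to 4.21), and Rag1 had 0 UMIs against 80. The MCAO cells lay mainly in the cluster led by Fcer2a and the sham cells in that led by Ms4a1. Jchain, the antibody joining chain gene, had 0 UMIs against 3584, of which 93.1% lay in 1 of the 4 sham cells that held any.

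Neutrophil-lineage cells of the MCAO 1 week pool (75 cells against 144) had 12 of 13 inflammatory genes higher, with a median log2 ratio of 1.24 (1.08 to 1.49; sham over sham 0.05). Ccl4 was 2.93 times higher (2.42 to 3.55), Il1b was 2.15 times higher (1.97 to 2.35) and Ptgs2, which encodes the inducible cyclooxygenase, was 2.80 times higher (2.12 to 3.71). The immediate early and heat shock list, which rises during tissue dissociation, was higher beside them. It had 12 of 15 members higher and a median of 0.71 (0.49 to 0.75). Whether dissociation bears on the inflammatory genes was not tested. Granule genes, which are made while neutrophils mature, had 12 of 13 members lower and a median of -0.82 (-0.94 to -0.72; sham over sham -0.04), with the cathelicidin gene Camp at 2.22 times lower (2.13 to 2.32) and Fcnb at 7.70 times lower (3.43 to 21.4). The class was not the same mixture in the pools: a cluster led by Ltf, Camp and Ngp held 40 sham and 10 MCAO cells and one led by Retnlg, with Cxcr2, held 78 and 57. A granulocyte precursor cluster led by the azurophil granule genes Mpo, Elane and Prtn3 held 25 and 3, and another precursor cluster, with Camp and Fcnb among its leading genes, held 1 and 5. Changes within cells were therefore not separated from the mixture. Upp1 was 13.2 times higher (6.46 to 30.6), with UMIs in 11 MCAO cells, and Cstdc4 was 5.66 times higher (4.36 to 7.40), with UMIs in 17.

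The same question was asked at 3 weeks, with the MCAO and sham pools in different libraries. The macrophage differences in MHC class II seen at 1 week were small here: H2-Aa was 1.08 times lower (1.06 to 1.11) and Cd74 1.18 times lower (1.16 to 1.19). Macrophages again had 17 of 19 interferon response genes higher, with a median log2 ratio of 0.41 (sham over sham -0.06), and Irf7, a transcription factor of that response, was 2.57 times higher (2.09 to 3.19). The immediate early and heat shock list, which rises during tissue dissociation, had 14 of 17 members lower in these macrophages. Its median was -0.43 (-0.49 to -0.38), against 0.08 for sham over sham. The heat shock gene Hspa1a was 5.41 times lower (4.60 to 6.34) and the immediate early gene Fos 1.10 times lower (1.06 to 1.14). Mmp9 was 80.2 times lower (54.2 to 122). Lyz1 was 30.5 times higher (8.41 to 252), the complement factor gene Cfb was 12.8 times higher (4.99 to 47.2) and Acta2 was 33.2 times higher (5.93 to 1313), each from 4 or fewer sham cells with a UMI. Retnla was at least 18.3 times higher, with UMIs in 34 of 2152 MCAO macrophages and 0 of 252 sham macrophages. The MCAO macrophages lay in clusters led by C4b and Cd163 (1139 cells), by Igfbp4 and Ccl8 (691) and by Tppp3 and Emp1 (322), and 143 of 252 sham macrophages in that led by Pla2g2d.

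In monocytes and DCs at 3 weeks the interferon response list had 18 of 19 members higher in the MCAO pool, with a median log2 ratio of 1.39 (1.09 to 1.61; sham over sham -0.43). Ifit3 was 9.01 times higher (4.13 to 24.6), Isg15 was 4.18 times higher (3.01 to 5.98) and Cxcl10 was 2.66 times higher (1.92 to 3.79). Monocyte genes had 8 of 10 members lower and a median of -1.82 (-2.05 to -1.69; sham over sham -0.22): Ly6c2 was 3.17 times lower (2.82 to 3.55) and Plac8 was 4.87 times lower (4.41 to 5.38). The class was not the same mixture in the pools: a cluster led by Ace and Apoc2, with Plac8 among its leading genes, held 48 of the 124 sham cells, while one led by Plac8, with Ly6c2, held 111 of the 1832 MCAO cells and one led by Sirpb1c held 858. MHC class II genes had a median of 0.72 (sham over sham 0.14) with 8 of 10 members higher. The complement list had 5 members higher and 4 lower, and its median of 2.56 (1.94 to 2.71; sham over sham -0.55) rested on C1qa at 8.13 times higher (6.78 to 9.82), C1qb and C1qc, which macrophages also express. Border macrophage genes were higher beside them, by a median of 1.27, with Mrc1 at 3.33 times higher (2.51 to 4.50), and both medians reversed with a looser cell filter, at -0.15 for complement and -0.17 for border macrophage genes. Mpo and Elane, genes of granulocyte precursors, were higher from 13 and 10 of 1832 cells.

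NK cells at 3 weeks (136 against 56 cells) had fewer transcripts of cytotoxicity and more of tissue residency in the MCAO pool. All 10 cytotoxicity genes were lower, with a median log2 ratio of -1.51 (-1.76 to -1.37; sham over sham 0.21): the granzyme genes Gzma and Gzmb were 3.92 (3.68 to 4.17) and 3.99 (3.35 to 4.75) times lower and the perforin gene Prf1 was 3.93 times lower (3.20 to 4.84). The residency list had 4 members higher and 2 lower, with a median of 2.12 (1.72 to 2.48), or 1.61 with Itga1, which had 0 sham UMIs, set at its bound. Cxcr6, a chemokine receptor gene of resident lymphocytes, was 15.1 times higher (4.08 to 126). S100a4 was at least 38.3 times higher and Il7r at least 9.14 times higher. Zeb2 was 8.40 times lower (4.88 to 15.0), Itgam was 6.64 times lower (4.12 to 10.9) and Klrg1 was 6.70 times lower (4 to 11.5), 3 genes of terminally differentiated NK cells, but the log2 ratio of Klrg1 moved from -2.73 to -0.58 with every cell thinned to 1000 UMIs. In the MCAO pool 44 of the 136 cells formed a subcluster led by Gzmc, and a similar subcluster of the sham library, with 5 cells of this sham pool, stayed unnamed and outside the class, so no fold is given for Gzmc. With subsets named without the extra rules, which counts both subclusters as NK cells, the residency median was 1.38 and the cytotoxicity median stayed within its interval.

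Among the smaller 3-week classes, ILCs (99 against 53 cells) had 4 of 5 residency genes higher, with a median log2 ratio of 1.15, and the transcription factor gene Bhlhe40 was 6.92 times higher (5.08 to 9.65). By the size rule, Cd83 was at least 17.3 times higher, with UMIs in 27 cells, and Bcl2a1b at least 16.3 times higher. The B-lineage genes Vpreb1 and Cd79a were at least 25.1 and 22.3 times lower, from UMIs in 2 and 4 of the sham cells. B-lineage cells had the homing genes Klf2 at 2.56 times lower (2.35 to 2.78) and S1pr1 at 2.88 times lower (2.24 to 3.73), while the inflammatory list was higher by a median of 2.32 together with the macrophage genes Ccl8 and Apoe, of which 73.5% and 42.1% of the UMIs lay in 1 cell each. Neutrophil-lineage cells (180 against 68) had MHC class II genes higher by a median of 5.92 (5.38 to 6.81): H2-Aa was 111 times higher (53.8 to 276) and Cd74 was 32.7 times higher (25.9 to 41.9). The macrophage gene Apoe was 30.9 times higher beside them (23.2 to 42.1), the class II median was 3.08 without Scrublet, and RNA of lysed cells was not subtracted, so these values are not shown to come from neutrophils. H2-Aa reached 2898 CPM (counts scaled to a common class total) in these cells and 15221 CPM in monocytes and DCs of the same library.

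The next comparison concerned CD45- dura cells, where all 4 pools shared a library but the sham pools were small, with 98 and 78 cells against 243 after MCAO at 1 week and 658 at 3 weeks. Fibroblasts were the largest class, at 60.2%, 57.6%, 53.8% and 44.7% of cells in the Sham 1 week, MCAO 1 week, Sham 3 weeks and MCAO 3 weeks pools, and MCAO over sham was 0.957 (0.701 to 1.32) at 1 week and 0.83 (0.599 to 1.18) at 3 weeks. Arachnoid or border cells, which line the face of the dura towards the brain, were 106 cells or 16.1% of the MCAO 3 weeks pool and 2, 6 and 0 cells in the others, where 0 of 78 cells has an upper bound of 4.62%. Blood endothelial cells had ratios of 2.26 (0.861 to 7.49) and 0.914, so no difference was detectable at this depth. Erythroid cells were 12.2%, 3.70%, 14.1% and 0.152% of the Sham 1 week, MCAO 1 week, Sham 3 weeks and MCAO 3 weeks pools. Cells without a hashtag call were 72.0% of erythroid cells (85 of 118) and 53.3% of osteogenic cells (49 of 92), against 34 of 148 arachnoid or border cells, so fewer than 50% of the first 2 could be given to a pool. Of the MCAO 3 weeks pool, 23.9% stayed unnamed, including 98 cells of a cluster led by the contractile genes Actg2 and Acta2 that held 12, 1 and 2 cells of the other pools.

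Fibroblasts had more matrix RNA after MCAO at both times. At 1 week 16 of 18 extracellular matrix genes were higher, with a median log2 ratio of 1.02 (0.86 to 1.17; sham over sham 0.26), and at 3 weeks 17 of 18, with a median of 0.98 (0.85 to 1.14), or 0.78 with Tnc at its bound. The collagen genes Col1a1 and Col1a2 were 4.08 (3.83 to 4.34) and 2.67 (2.52 to 2.82) times higher at 1 week, and 2.94 (2.77 to 3.12) and 2.41 (2.27 to 2.55) times higher at 3 weeks. Among genes named by the size rule, the smooth muscle genes Tagln and Acta2 were 92.7 (39.7 to 286) and 12 (8.77 to 17) times higher at 1 week, and Tagln was 18.6 times higher (7.96 to 57.5) at 3 weeks. The log2 ratios at 1 week moved from 6.40 to 4.55 for Tagln and from 3.57 to 4.34 for Acta2 with every cell thinned to 1000 UMIs, and to 6.80 and 5.04 without the cell with the most UMIs of the gene in each pool. In mural cells, which normally express these genes, Tagln stood at 1295 CPM at 1 week and in the MCAO fibroblasts at 1257 CPM. Igfbp2, an insulin-like growth factor binding protein gene, was 20.5 (7.93 to 75.6) and 35.7 (12.2 to 173) times higher. The fibronectin gene Fn1 was 8.17 times higher (5.43 to 12.9) at 3 weeks and the matricellular gene Ccn3 9.01 times higher (5.25 to 17). The lubricin gene Prg4 was 38.0 times higher at 1 week (6.73 to 1512), with UMIs in 31 MCAO cells and 1 sham cell, and the collagen gene Col6a5 was 62.5 times lower (20.1 to 314). The red cell gene Hbb-bs was at 47.9 CPM in MCAO and 1412 CPM in sham fibroblasts at 1 week, and at 76.4 CPM in sham fibroblasts at 3 weeks.

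At 3 weeks MCAO fibroblasts also had more antigen presentation RNA. MHC class I genes had all 9 members higher, with a median of 0.51 (sham over sham -0.03), and class II genes all 6, with a median of 1.90 (1.31 to 2.79), or 1.77 with H2-Eb1, which had 0 sham UMIs, at its bound; Cd74 was 5.47 times higher (2.63 to 13.7). The interferon response list had 13 of 14 members higher and a median of 0.98, or 0.71 with 1 gene at its bound, and Isg15 was 8.05 times higher (3.12 to 29.7). The immediate early and heat shock list was lower, with medians of -0.66 at 1 week and -0.97 at 3 weeks, against -0.38 for sham over sham. The 42 sham fibroblasts of this comparison held 274993 UMIs and the 294 MCAO fibroblasts 3323839. At 3 weeks 135 MCAO and 5 sham fibroblasts lay in a cluster led by Cfb and Cxcl14, and 77 and 23 in one led by Chad and Cilp2.

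The last comparison set lymphocytes of the brain against those of the dura 3 weeks after MCAO. Among named T cells, γδ T cells were 10.3% in brain and 35.5% in dura, 3.45 times lower in brain, at a ratio of 0.289 (0.249 to 0.337). CD4 T cells were 34.8% and 24.7%, a ratio of 1.41 (1.23 to 1.62), or 1.20 without a brain subcluster that held CD8 transcripts, CD8 T cells were 21.9% and 14.2%, a ratio of 1.54 (1.29 to 1.85; 2.93 at a finer clustering and 6.87 with the libraries clustered together), and regulatory T cells were 33.1% and 25.6%, a ratio of 1.29 (1.13 to 1.48). These shares were of 3124 brain and 1062 dura cells. The dura CD4 T cells included a subcluster of 119 cells led by Trav1, with 3 CD4 T markers detected. It may hold other T cells. No ratio without it was computed, so the value of 1.20 leaves out cells on the brain side only. Of T cells, NK cells and ILCs together, NK cells were 15.9% and 9.96%, ILCs 2.27% and 7.25%, and unnamed cells 24.6% and 4.98%. An unnamed brain subcluster of 831 cells was led by Klra1, Klra7 and Cd160. Its leading genes also included Ccl5 and Trgv2, a gene segment of the T-cell receptor γ chain. Most of its cells came from clusters named T cell. It stands outside the shares of named T cells, and these, the γδ T cell share included, could change with it. Unnamed dura clusters with T cell genes, described above at 3 weeks, were not clustered again. They stand outside all these shares, which could change with them. The regulatory T cell share reversed to a ratio of 0.958 at a coarser clustering and 0.924 with only cells positive for their tag, and tissue, dissociation, the CD11b gate and library cannot be told apart here.

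The immediate early and heat shock genes were lower in brain than in dura in every one of the 7 lymphocyte classes compared. The median log2 ratio was -2.27 (-2.56 to -1.99) in NK cells, -2.50 in CD8 T cells, -2.88 in regulatory T cells, -2.93 in B-lineage cells, -2.94 in γδ T cells, -3.48 in CD4 T cells and -4.81 (-5.21 to -4.38) in ILCs. Of the measured members, 13 to 15 in each class, 1 in ILCs was higher in brain and none in the other classes. Dusp1, a phosphatase gene of this group, was 103 times lower in brain NK cells (71.3 to 153) and 68.9 times lower in brain CD8 T cells (44.5 to 112), and Junb was 39.2 times lower in brain γδ T cells (34.0 to 45.3). The dura was digested with enzymes and the brain was homogenised on ice with no enzyme named. A brain subcluster of 80 T cells led by Ccl4, Egr1 and Nr4a1 stayed unnamed and outside these classes. All other brain and dura values stand beside this difference.

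Regulatory T cells of the brain had fewer transcripts of tissue residency and more of circulation. The residency list had 7 of 8 members lower, with a median log2 ratio of -1.55 (-1.83 to -1.27), including Itgae, the integrin αE gene, at 4.03 times lower (3.47 to 4.68) and Cxcr6 at 2.15 times lower (1.71 to 2.70). The circulation list had 7 of 8 members higher, with a median of 0.99 (0.72 to 1.18): the transcription factor gene Tcf7 was 6.95 times higher (4.74 to 10.6) and Klf2 was 2.22 times higher (1.87 to 2.64). The list of regulatory T cell genes had 12 of 13 members lower and a median of -0.59. In it Foxp3, the lineage factor gene, was 1.48 times lower (1.36 to 1.60) and Ctla4 2.39 times lower (2.17 to 2.62). Areg, which encodes the repair factor amphiregulin, was 169 times lower (125 to 233), with UMIs in 33 of 1033 brain and 212 of 272 dura cells. It leads the dura cluster of these cells. Art2b was at least 13.8 times higher and Gimap4 6.88 times higher (5.15 to 9.41) in brain. A brain subcluster of 254 cells led by Ecm1 and Ikzf4, with Ccr7 among its leading genes, stood beside one of 779 cells led by Klrg1, and the dura had 1 subcluster of such cells.

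CD4 T cells differed in the same lists. In brain the circulation list had 7 of 8 members higher, with a median of 1.81 (1.61 to 2.04), and the residency list had 7 of 9 lower, with a median of -1.73 (-1.88 to -1.39). All 8 Type 17 genes were lower, with a median of -4.04. Of the 262 dura CD4 T cells, 119 lay in a subcluster led by Trav1 and Tcrg-V4, and of the 1087 brain cells 234 lay in one led by Igfbp4 and Dapl1 with Ccr7, Lef1 and Cd8b1, of which 143 held UMIs of Cd8a or Cd8b1 and 29 of Cd4, against 43 and 475 of the other 853. This subcluster, named CD4 by its marker score, so held CD8 T cells, and without it the circulation median was 1.74. The dura subcluster led by Trav1 had 3 CD4 T markers detected and 1 of them, Cd40lg, among its leading genes. Tcrg-V4 belongs to the T-cell receptor γ chain, so this subcluster may hold T cells other than CD4 T cells. No Type 17 median without it was computed. The mixtures differed, and clustering the libraries together moved the Type 17 median to -0.68. γδ T cells had all 6 circulation genes higher in brain, with a median of 1.12 (0.77 to 1.61) and S1pr1, which drives exit from tissue, at 23.4 times higher (9.74 to 73.3), and 4 of 6 residency genes lower, with a median of -1.47. Their Type 17 genes differed little, with a median of -0.13, and Il17a was 1.84 times lower (1.49 to 2.29). The kinase gene Lck was 40.3 times higher (18.2 to 111), with UMIs in 101 brain and 3 dura cells.

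CD8 T cells and NK cells had residency medians of -0.56 and -0.54, and the circulation median of CD8 T cells was -0.35, which reversed to 0.52 at a finer clustering. In CD8 T cells 7 of 8 checkpoint genes were lower in brain, with a median of -0.85, with the inhibitory receptor gene Pdcd1 at 1.63 times lower (1.26 to 2.09), and Gzmk was 1.39 times higher (1.17 to 1.67). In NK cells 10 of 12 cytotoxicity genes were lower, with a median of -0.59 and Gzma at 2.16 times lower (2.05 to 2.27). ILCs had 4 of 5 residency genes lower, with a median of -2.36 (-2.77 to -1.58). B-lineage cells of the brain (3127 cells) had all 10 MHC class II genes higher than those of the dura (356 cells), with a median of 1.20, and H2-Aa was 2.57 times higher (2.47 to 2.68). All 10 B-cell development genes were lower, with a median of -2.30, and Rag1 was 177 times lower (46.3 to 1508), with 2 brain UMIs, but 70 of the dura cells formed a precursor cluster and no brain cluster was named so. Icosl, the ligand gene of the costimulator ICOS, was 9.57 times higher (5.45 to 18.6) and Ccr6 was 6.08 times higher (3.82 to 10.3). Chemokine genes of macrophages, such as Ccl8, were lower in brain B cells, and 73.5% of its dura UMIs lay in 1 cell. A brain cluster of 53 cells led by Jchain was named plasma cell and stayed outside this class, while the dura cells with Jchain UMIs stayed inside, so plasma-cell genes are not compared.

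**Figure D2:**
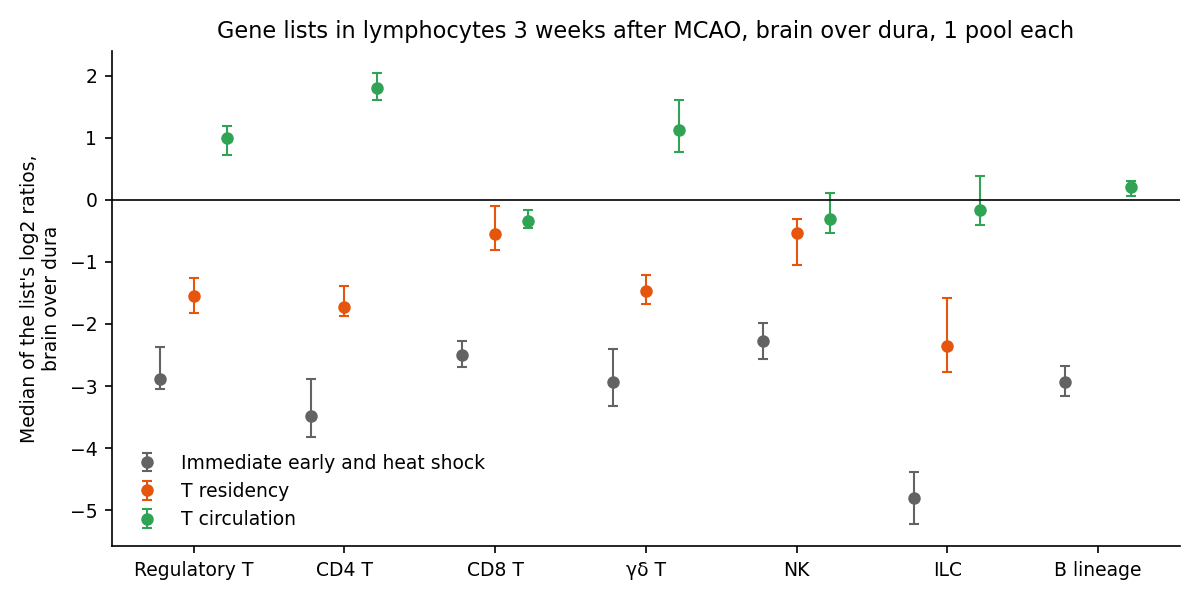
Points give the median log2 ratio, brain over dura (y axis), of 3 gene lists in 7 lymphocyte classes (x axis) 3 weeks after MCAO, and bars are 95% intervals for counting error. The immediate early and heat shock points lie between -2.27 and -4.81, and the circulation points lie above 0 in regulatory T, CD4 T, γδ T and B-lineage cells.

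The coordinates of genes named first in each comparison, from the GENCODE M21 annotation of GRCm38, which is mm10, all cover protein-coding genes. H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823, beside H2-Eb1 (ENSMUSG00000060586) from 34305867 to 34316674. Retnla (ENSMUSG00000061100) lies on chromosome 16 from 48842551 to 48844461, Plaur (ENSMUSG00000046223) on chromosome 7 from 24462484 to 24475968 and Mmp9 (ENSMUSG00000017737) on chromosome 2 from 164940780 to 164955850. Tagln (ENSMUSG00000032085) lies on chromosome 9 from 45929619 to 45936058, Igfbp2 (ENSMUSG00000039323) on chromosome 1 from 72824503 to 72852474 and Areg (ENSMUSG00000029378) on chromosome 5 from 91139599 to 91148432. The values are sums of UMIs over whole genes, so no exon or transcript was singled out.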

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

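The tests below were chosen after the result was seen, except 1 on the leading tag of arachnoid cells, which was written before and is void. The test that replaced it was changed after its values were seen. Of 4 versions of the arachnoid test, 2 left the loss of cells open and 2 excluded it by their rule. The last is given, and no verdict is drawn from it because the versions disagree.

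The share of B-lineage cells was lower in the MCAO pool at 1 week, and the design names stroke as the biological explanation. Loss as cells without a hashtag call was excluded, because adding all 19 such B-lineage cells gave a share of 5.22% (4.24 to 6.36), below the lower bound of 21.8% for the Sham 3 weeks pool. Dilution by phagocytes alone was excluded, because B-lineage cells per T cell, NK cell or ILC had a ratio of 0.151 (0.116 to 0.193), with 0.316 in the MCAO pool, 2.10 in the Sham 1 week pool and 1.42 in the Sham 3 weeks pool. Less skull marrow in the MCAO pool cannot be told apart from stroke: granulocyte precursors, also of marrow, had a ratio of 0.239 (0.0935 to 0.543) against the Sham 1 week pool but 1.07 (0.287 to 4.85) against the Sham 3 weeks pool. These ratios rest on 8, 26 and 4 called precursors of the MCAO 1 week, Sham 1 week and Sham 3 weeks pools. Of the 509 neutrophil-lineage cells, which include the precursors, 222 had no call. Among CD45- cells of the same pools, erythroid cells had ratios of 0.302 (0.113 to 0.782) and 0.263 (0.0962 to 0.697) against the 2 sham pools and osteogenic cells, of the skull, 0.0807 (0.00171 to 0.721) and 0.0535 (0.00116 to 0.441), which go with less skull or marrow, but rest on 12 or fewer called cells per pool, while 85 erythroid and 49 osteogenic cells had no call. The cluster of mature B cells led by Fcer2a had 0.324 (0.237 to 0.437) against the Sham 1 week pool, but 0.688 (0.466 to 1.02) against the Sham 3 weeks pool, with sham over sham at 0.471.

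Arachnoid or border cells were nearly confined to the MCAO pool at 3 weeks, at 2 of 176 cells (1.14%) in both sham pools. Loss of sham cells of this class as cells without a hashtag call did not account for the whole difference under the limits below, but it was not excluded. Of the 34 such cells, 6 had at most 42 counts of the MCAO 3 weeks tag, the 95th percentile of called sham cells, and adding them to the sham pools gave a share of 4.40% (1.92 to 8.48), below the lower bound of 13.4% in the MCAO pool. Cells without a call carried more of this tag than called sham cells, at medians of 62 and 2 counts, so a limit was also taken from 96 cells without a call in classes of which at most 10% of called cells came from the MCAO 3 weeks pool, a limit set after the tag counts of the classes were seen. Of the 96 cells, 85 were erythroid, with a median of 24 counts of this tag, against 97 in fibroblasts without a call. This limit may therefore be too low for other classes. At 100.5 counts 13 cells were added and the share was 7.94% (4.51 to 12.8), also below 13.4% but close to it. The 34 cells had a median of 108 counts of this tag, against 2.5 in 8 called cells of the class in other pools, and of 1 for sham tags, with 9 the highest. A limit from all 492 cells without a call gave 16.3% and is void, because 477 of them had this tag highest. The test written before asked which tag stood furthest above its median in cells without a call and gave 11.2% (7.17 to 16.5), and it is void because the sham medians were 0, so that single counts decided it. More of the border taken with the dura in that pool, at a share of 16.1%, cannot be told apart from stroke, since each pool had 1 dissection.

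The immediate early and heat shock list was lower in brain than in dura in 7 classes. For the 3 classes also compared within the dura, the highest median of MCAO over sham at 3 weeks was 0.54 (upper bound 0.78, ILCs), below the difference to the brain. Those pools were in different libraries, so a library difference could hide a stroke effect. Stroke in the dura as the whole cause was therefore not excluded. Enzyme digestion of the dura stays open, with medians between -2.27 and -4.81, because tissue, gate and library were confounded with it. Tissue as the biological explanation was not tested.

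Lists with opposite directions at 1 and 3 weeks were set apart as differences between the time points, which were not tested. Plasma-cell genes in the B lineage had medians of -1.69 and 0.97, MHC class I genes in macrophages -0.34 and 0.37, and cell cycle genes in monocytes and DCs 0.95 and -0.87. For the last, sham over sham was 1.57, larger than either, so the sham pool used bears on the sign, and the 3-week value was 0.46 at resolution 2. Cells without a hashtag call, which no comparison used, included 1134 named CD45+ cells and 385 named CD45- cells.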

How the results depend on the processing

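Tests of named cells as the denominator, of subset naming without the extra rules, of brain CD4 T cells without the subcluster with Cd8b1, of unnamed clusters counted in the family of their leading genes and of genes without the cell with the most UMIs were chosen after the results were seen, and the other alternatives were fixed beforehand. Of 252 values of 29 shares, 205 stayed near the main value, 39 moved and 8 reversed. Of 1232 values of 105 list medians, 940 stayed, 270 moved and 22 reversed. Of 760 values of 190 named genes, 661 stayed, 97 moved and 2 reversed. Reversed values are listed below for every result. Moved values are listed only for the larger families, the arachnoid share, the T subset shares, hashtag assignment and the list with the largest median of each class. Where macrophage, NK cell or ILC shares, other list medians or single genes moved without reversing, those values are not listed here, and the move can exceed the printed interval. The lower B-lineage share at 1 week kept its direction, between 0.109 and 0.156, as did the higher phagocyte share at 1 week, between 2.07 and 2.43. A further 59 alternatives gave no value because too few cells or genes were left. No paired analysis was possible because each group was 1 pool and no test was run. Depth limited the small sham classes, since genes with fewer than 30 UMIs in both sums together were not measured, and the unit of 1 pool limits every comparison to these mice. The cause was not tested for any value below, except where stated.

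Shares at 3 weeks moved most. With joint clustering of the CD45+ libraries, the ratio was 0.156 for the B lineage at 1 week and, at 3 weeks, 1.71 for phagocytes and 2.11 for mast cells and basophils, and the CD8 T share, brain over dura, was 6.87. The Gaussian mixture assigned 70.4% of CD45+ barcodes in place of 67.4% and 74.7% of CD45- barcodes in place of 60.7%. With it the neutrophil-lineage ratio at 1 week was 0.548, the mast cell ratio at 3 weeks 1.68 and the arachnoid share 12.99%. With only tag-positive cells, the ratios at 3 weeks were 0.0326 for the B lineage and 1.59 for phagocytes, and brain over dura was 2.16 for CD4 T cells, 0.0830 for γδ T cells and 0.924 for regulatory T cells. B-lineage cells were mostly tag-negative in that dura library (11.0% positive, against 80.8% of T cells, NK cells and ILCs), which lowers their share by construction, and in the brain library (6.84% against 79.0%), so the brain B-lineage values rest mostly on tag-negative cells. Phagocytes at 3 weeks had a ratio of 1.55 with the looser filter, 1.54 with the stricter filter, 1.02 at resolution 0.5 and 1.56 among named cells. Mast cells at 3 weeks had 2.59 with the stricter filter and 2.18 without Scrublet, and monocytes and DCs had 0.464 at resolution 0.5. The arachnoid share was 21.2% of named cells. With unnamed clusters counted in the family of their leading genes, the ratios at 3 weeks were 0.590 for the neutrophil lineage and 1.47 for T cells, NK cells and ILCs, and the ratio for mural cells reversed to 1.995.

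Brain over dura, the CD4 T share was 1.63 without Scrublet, 2.35 at resolution 0.5 and 1.20 without the subcluster with Cd8b1. The CD8 T share was 1.26 without Scrublet, 2.93 at resolution 2 and 2.10 without the extra rules. The γδ T share was 0.212 at resolution 0.5 and 0.183 at resolution 2, and the regulatory T share was 0.958 at resolution 0.5 and 1.03 without the extra rules.

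For list medians at 1 week, B-cell development genes had -1.64 with the mixture, -0.62 at resolution 2, -1.35 with at least 100 UMIs and -1.73 with thinned cells. MHC class II genes in macrophages had -1.52 with the stricter filter, -1.77 and -1.98 at resolutions 0.5 and 2, -1.72 without the 20 most abundant genes and -1.47 with thinned cells. In monocytes and DCs, cell cycle genes had 0.37 with the looser filter, 0.39 at resolution 0.5 and 0.47 with at least 100 UMIs, and complement genes, 0.41 in the main setting, reversed to -0.094 with the looser and -0.0022 with the stricter filter. In the neutrophil lineage, inflammatory genes had 0.76 with the mixture and 0.93 with thinned cells, and complement genes, 0.97 in the main setting, reversed to -0.16 with the stricter filter, -0.24 without Scrublet, -0.57 at resolution 2 and -0.037 with thinned cells. Matrix genes of fibroblasts had 0.60 with thinned cells.

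At 3 weeks, immediate early and heat shock genes in macrophages had -0.59 with the looser and -0.60 with the stricter filter, -0.14 without Scrublet, -0.56 and -0.53 at resolutions 0.5 and 2, -0.52 with thinned cells and -0.36 with TMM. In monocytes and DCs, complement genes had 1.69 with the mixture, -0.15 with the looser and 0.80 with the stricter filter, 0.66 without Scrublet, 1.18 with at least 10 UMIs, 1.34 with thinned cells and 2.80 with TMM. In the same class border macrophage genes had -0.17 and -0.47 with the looser and stricter filters, inflammatory genes -0.30 with the looser filter, and cell cycle genes 0.46 at resolution 2. Residency genes in NK cells had 3.41 with the looser filter, 1.36 without Scrublet and 1.38 at resolution 0.5 and again without the extra rules. Inflammatory genes in the B lineage had 3.63 without Scrublet and 1.59 with at least 10 UMIs, and MHC class II genes in the neutrophil lineage had 3.08 and 5.21. Plac8 in the neutrophil lineage had a log2 ratio of 0.039 with thinned cells, and Col15a1 in fibroblasts 0.31 without the cell with the most UMIs, both reversed.

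For brain over dura, inflammatory genes in the B lineage had -1.06 with joint clustering, -9.00 with tag-positive cells, -3.73 with the stricter filter and -9.16 without Scrublet. In CD4 T cells, cytotoxicity genes, 0.37 in the main setting, reversed to -1.48 with joint clustering, -0.996 and -0.070 with the looser and stricter filters, -0.14 at resolution 2, -0.27 with thinned cells and -0.16 without the subcluster with Cd8b1. Regulatory T cell genes in CD4 T cells, -0.81 in the main setting, reversed to 0.22 with joint clustering and 0.12 at resolution 0.5, and interferon genes, 0.54, to -0.082 with thinned cells. Type 17 genes in CD4 T cells had -0.68 with joint clustering, -5.11 at resolution 2, -4.59 and -3.33 with at least 10 and 100 UMIs and -3.18 with thinned cells. Circulation genes in CD8 T cells reversed to 0.69 with joint clustering and 0.52 at resolution 2. Immediate early and heat shock genes in CD8 T cells had -1.15 with joint clustering, -2.70 with tag-positive cells, -2.01 at resolution 2, -1.74 with at least 100 UMIs and -1.95 with thinned cells, those in regulatory T cells had -2.30 with at least 100 UMIs, and those in NK cells had -2.64 with at least 10 UMIs and -2.69 with thinned cells.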

Other observations

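No test is reported in this part.

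Several smaller leukocyte groups of the first dura library are given as counts out of 1367, 1761 and 942 cells. ILCs, which release cytokines without antigen receptors, formed a subcluster led by Rnf128, Il1rl1 and Il17rb. It held 65, 14 and 48 cells of the Sham 1 week, MCAO 1 week and Sham 3 weeks pools. Another subcluster named ILC, with Il5, Csf2, Il13 and the histone gene Hist1h1b among its leading genes, held 6, 30 and 5. Its leading genes also included the B-lineage genes Igkv6-32, which stood first, and Cd79a, so it may hold a mixture of cells. A subcluster led by Gzmc, Xcl1 and Crtam, left unnamed, was 9, 32 and 5. CD8 T cells led by Cx3cr1 and Klf2 were 23, 3 and 9 cells. A cluster of osteoclast genes (Ctsk, Acp5, Atp6v0d2, Mmp9) held 4, 16 and 1 cells, and a macrophage cluster led by the interferon genes Ifit3 and Rsad2 held 7, 50 and 5. Dendritic cells led by Xcr1 and Clec9a, which cross-present antigen, were 18, 95 and 22 cells, those led by Fscn1 and Ccl22, a migratory state, were 3, 18 and 1, and a cycling cluster held 26, 138 and 29.

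At 3 weeks after MCAO, a dura cluster of 387 phagocytes led by Ccl3, Tmem119, Olfml3 and Cx3cr1, genes of microglia and related macrophages, was counted as phagocytes without a class. In the brain pool, a cluster of 487 cells led by Apoe, Fcrl5 and Mzb1, 283 T or NK cells led by Ifit3, 76 cells led by Ifit3 and Oasl1 and a subcluster of 319 NK cells led by Gzmc were present. Brain B cells lay mostly in a cluster of 2229 cells led by Fcer2a and Ighd, and 115 lay in one led by Il4i1, Nfkbid, Cd83 and Nr4a1. Plasmacytoid DCs were 125 cells and mast cells 26. Among CD45- dura cells, mural cells, the pericytes and smooth muscle of vessels, were 8, 27, 4 and 3 cells of the Sham 1 week, MCAO 1 week, Sham 3 weeks and MCAO 3 weeks pools, and osteogenic cells led by Bglap were 5, 1, 6 and 31.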
